A study of Homo sapiens with 6 samples.

How the data were processed

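KYSE150 cells were plated in dishes, given vehicle or 1 µmol/L omipalisib on the following day, harvested 8 h later with trypsin and shipped on dry ice for sequencing, per the labels' protocols. Poly-A RNA was captured on oligo-dT beads, fragmented, copied with random primers, and sequenced as single-end 50 bp reads on a BGISEQ-500, per the labels' protocols. Nothing in these protocols says that strand was kept, so genes that overlap, or lie antisense to another gene, are uncertain. The labels give 3 control and 3 omipalisib samples, and each column of the tables was matched to its sample by the name in its header.

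The authors deposited a gene table and a transcript table. Per the file headers, both hold read counts per sample, which are estimated counts with 2 decimals, and a further value per sample. By its values, this further column, deposited by the authors, is FPKM: it follows the estimated counts by a constant per gene, up to the library total. HISAT is named in the submitters' processing notes, without a version; the counting tool, genome build and annotation are not given in the sources used here. For this reason no coordinates are printed. The authors' mean columns were not used. The gene table has 27965 genes, 24036 with an NCBI gene ID and 3929 with an ID of the sequencing provider, and 1808 genes had 0 reads in every sample. The transcript table has 189949 entries, 92909 with RefSeq accessions. Each gene value equals the sum of its transcripts within 0.07 reads. A spreadsheet had turned 26 symbols into dates; all 26 were restored from their gene IDs. Of the NCBI gene IDs, 23332 were found in the RefSeq gene table of GRCh38.p14, which was used only for names, gene types and overlaps. IDs of the provider held 4.88% to 6.16% of reads per sample, and the largest entry 3.35% to 4.62%.

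Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr, scaled by TMM, and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over all tested genes; a gene was called at an adjusted p of 0.05. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F. CPM values are TMM-normalised, with SD over 3 libraries. Transcripts were tested in the same way as a further summary of the same reads. Adjusted p-values given without another tool's name are from this edgeR test.

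Before the data were examined, 36 gene lists were fixed from general knowledge of PI3K and mTOR signalling, squamous epithelium and other cell types. The 33 with at least 5 tested members were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01 and adjusted over the 33 lists. Camera with an estimated correlation and fry were alternatives. Some genes stand in more than 1 list, such as INSR, ERBB3, GADD45A, BBC3 and GUSB. The genes named in the text follow a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM, non-overlapping groups and a symbol not starting with LOC, then 13 fixed pathway genes whatever their values, and up to 4 examples per list with the largest change among called members of at least 1 CPM. Where 5 or fewer members of a list moved in a direction, the others of them are named too, having been chosen after their values were seen. Some genes that the rule or these counts cover are left unnamed in the text, whatever their values; they stay in all counts and tests.

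Alternatives fixed in advance were RLE size factors, library size only, no filter, a filter of at least 10 CPM in 3 samples, DESeq2 1.42.0, limma-voom, a replicate block, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1, genes summed from transcripts, and leaving out each library. Offsets for transcript length and GC content, and list tests without a minimum size, were added after seeing the data. Lengths came from the ratio of counts to FPKM, for entries with FPKM of at least 0.1 and at least 5 reads, and GC content from GENCODE transcripts matched by symbol; 83.6% of tested genes and 99.7% of tested list members had both values. Counts of genes assigned to near-identical copies (HSPA1A and HSPA1B, histones, tubulins, metallothioneins and genes with processed pseudogenes such as ACTB, PGAM1 and RPS26) are uncertain where reads could have been split.

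The scripts were tested on simulated counts drawn from these libraries' means and dispersions. For the gene comparison, with 200 of 16255 genes changed, edgeR recovered 91% of genes with a log2 fold change of 2 and 67% of those with 1, and 12.7% of its calls were false, above the nominal rate; DESeq2 recovered 93% and 71% with 20.8% false. For the transcript comparison, with 200 of 68309 changed, edgeR made no correct call, while 62.5% of those with a log2 fold change of 2 had an unadjusted p under 0.05 and estimates were centred on the simulated values (2.03 and -1.99). Only 200 entries were changed in each of these simulations, fewer than were called in the data, so these rates need not hold there. A simulated shift of 0.6 in the lysosome list was found by camera, with 0 of the 32 other lists called. The simulated genes varied independently, so this cannot show how camera behaves with correlated genes.

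Pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom from 7.05 to 36.0 over genes), so no library repeats the reads of another; this does not show that they came from separate cultures. All 6 were counted as samples because the labels list them so. With totals of 21277270 to 21829209 reads, genes under 1 CPM rest on few reads and carry large counting error.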

Results

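Poly-A RNA was sequenced from KYSE150 cells, an established line from a human esophageal squamous cell carcinoma, after 8 h with 1 µmol/L omipalisib, a small molecule inhibitor of PI3K and mTOR kinases, or with vehicle. The comparison asks which transcripts the drug changed, in a study of growth inhibition of esophageal cancer cells through the PI3K, AKT and mTOR pathway. There were 3 control and 3 omipalisib libraries of single-end 50 bp reads. Estimated reads assigned to genes totalled 21829209, 21277270 and 21811176 in control libraries 1, 2 and 3, and 21575904, 21763592 and 21775076 in omipalisib libraries 1, 2 and 3. The leading principal component of log2 CPM (read counts scaled to library size) carried 52.1% of the variance and separated the groups, with scores of -46.8 to -34.0 in controls and 38.1 to 43.8 in treated libraries. The next component carried 17.0% and set control 1 (42.8) apart from control 2 (-38.7). The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples only, which may be technical.

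Among genes averaging at least 10 CPM, matrix metalloproteinases, interferon-induced genes and the atrophy-associated ubiquitin ligase gene FBXO32 rose most after 8 h of omipalisib. That average was over all libraries, so genes low in controls, such as MMP10, could pass on their treated values. The heat shock gene HSPA1A, the serine synthesis gene PSAT1 and the cell cycle phosphatase gene CDC25A were among the largest falls. The collagenase and stromelysin family gene MMP10 (NCBI gene 4319) went from 1.07 ± 0.21 to 54.0 ± 10.3 CPM (mean ± SD, n = 3 per group), a log2 fold change of 5.65 ± 0.21 (SE). MMP13 (gene 4322) rose 37.0-fold, from 1.45 ± 0.24 to 53.9 ± 6.0 CPM. FBXO32 (gene 114907) rose 8.17-fold, from 14.1 ± 1.3 to 115 ± 13 CPM, and the hyaluronan-degrading factor gene CEMIP (gene 57214) rose 8.99-fold. The cytokine gene IL6 (gene 3569) rose 7.38-fold, from 2.73 ± 0.06 to 20.2 ± 4.8 CPM. IFIT2 (gene 3433), IFIT3 (gene 3437) and OASL (gene 8638), which interferon induces, rose 22-fold, 8.45-fold and 7.07-fold. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these 8 genes ran from 3.66e-06 for MMP13 to 0.0195 for OASL. OASL missed the threshold without control 1 (adjusted p = 0.0657 by edgeR), control 2 (0.0608) or omipalisib 1 (0.0644).

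Among the falls, HSPA1A (gene 3303) went from 178 ± 9 to 21.6 ± 3.3 CPM, 8.26-fold lower, and its near-identical neighbour HSPA1B (gene 3304) was 5.80-fold lower; reads shared between these copies make either value uncertain. PSAT1 (gene 29968) fell from 176 ± 31 to 31.4 ± 3.1 CPM, and CDC25A (gene 993) from 65.1 ± 11.1 to 13.1 ± 2.0 CPM. TIGAR (gene 57103), a regulator of glycolysis, was 6.08-fold lower, the phosphatase gene PDXP (gene 57026) 6.56-fold lower, TMEM158 (gene 25907) 5.90-fold lower and the kinase gene TP53RK (gene 112858) 7.04-fold lower. Across these 8 genes the adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 8.22e-06 for HSPA1A to 0.0134 for TP53RK. Without control 2, TP53RK missed the threshold (adjusted p = 0.0526 by edgeR).

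In all, 6016 of 16561 tested genes passed an adjusted p of 0.05, 3011 higher and 3005 lower with omipalisib. Of these, 1365 changed at least 2-fold, 894 higher and 471 lower. The treated and control values of 51.2% of tested genes did not overlap, where chance gives 10%. With scaling by library size only, the split was 3754 higher and 2334 lower (61.7% against 50% higher), and the median log2 fold change of all genes was 0.13 in place of 0.03. Without omipalisib 1 the count was 3943, with 1885 higher, and without omipalisib 2 the number higher was 1942.

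**Figure D1:**
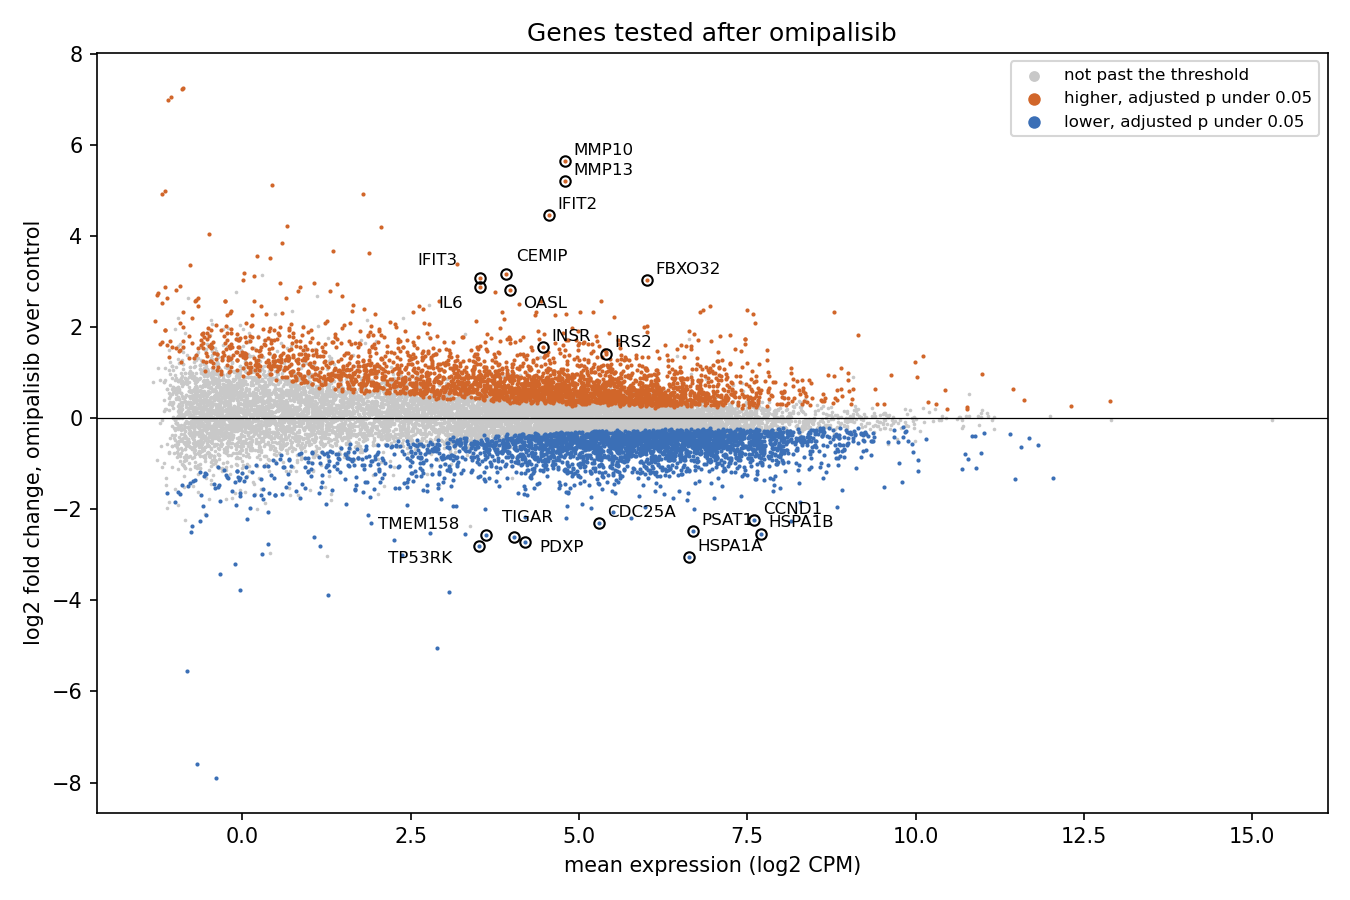
Log2 fold change (omipalisib over control, edgeR) against mean expression (log2 CPM) for the 16561 tested genes; each point is a gene, orange for the 3011 higher and blue for the 3005 lower genes at an adjusted p under 0.05, grey for the rest. Circled genes are the 8 largest rises and 8 largest falls among genes averaging at least 10 CPM over all libraries, with IRS2, INSR and CCND1.

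Genes that FOXO transcription factors activate, which AKT holds in check, rose as a group: 23 of 29 tested members rose and 1, GADD45A, fell (log2 fold change -0.63). Besides FBXO32, the death ligand gene TNFSF10 went from 0.41 ± 0.24 to 7.63 ± 2.99 CPM, KLF6 from 58.6 ± 6.8 to 304 ± 71 CPM and YPEL3 from 5.15 ± 1.76 to 29.1 ± 4.9 CPM. The list passed camera (adjusted p = 2.51e-16), with an adjusted p of 0.0551 with an estimated correlation. Adjusted over the list alone, the counts were again 23 higher and 1 lower. The genes of this list that rose also hold INSR, IRS2, ERBB3, PIK3IP1 and CDKN1B, so their rises given below are not separate results.

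Upstream of PI3K, the insulin receptor gene INSR (gene 3643) rose 2.94-fold, from 11.2 ± 0.6 to 32.9 ± 2.0 CPM, and its adaptor gene IRS2 (gene 8660) rose 2.67-fold, from 22.9 ± 2.2 to 61.2 ± 7.3 CPM. ERBB3 (gene 2065) rose 1.85-fold and the epidermal growth factor receptor gene EGFR 1.91-fold. Of 24 tested receptor tyrosine kinase genes, 9 rose and 2, EPHA2 and ROR1, fell (10 and 4 adjusted over the list alone; 4 fell without control 2, and 11 rose and 7 fell with length and GC offsets). That list did not pass camera (adjusted p = 0.0645; 0.624 with an estimated correlation); its adjusted p by camera was 0.00643 without control 1, 0.0256 without omipalisib 2 and 0.0464 with scaling by library size only.

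Genes of the PI3K, AKT and mTOR pathway itself went both ways, with 11 of 36 higher and 12 lower (11 and 14 adjusted over the list alone); the number higher was 5, 7 and 5 without omipalisib 1, 2 and 3, and 6 without control 3. RICTOR, which encodes a scaffold of mTOR complex 2, rose 3.71-fold (27.3 ± 8.0 to 101 ± 11 CPM), the kinase gene SGK1 2.90-fold and the mTOR inhibitor gene DEPTOR 2.20-fold. The kinase gene MTOR (gene 2475) was 1.42-fold lower, EIF4EBP1 (gene 1978), a translational repressor that mTOR phosphorylates, 1.36-fold lower, and the AKT phosphatase gene PHLPP2 2.18-fold lower. PIK3IP1 (gene 113791), which encodes a PI3K inhibitor, rose 1.68-fold. AKT1 (gene 207) was 1.30-fold lower and PIK3CA (gene 5290) 1.94-fold higher, with adjusted p of 0.0135 and 0.0461 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The edgeR call was lost for AKT1 without omipalisib 1 (adjusted p = 0.0681) or omipalisib 2 (0.0502), and for PIK3CA without control 2 or 3 (0.0554 and 0.0559) or omipalisib 1, 2 or 3 (0.111, 0.103 and 0.109). Control PIK3CA values were 9.84, 24.7 and 23.7 CPM. The list's camera adjusted p was 0.68 (0.831 with an estimated correlation), with a median log2 fold change of -0.19 (-0.09 without control 2 or with library size only), a mean of 0.02 and a test direction of lower.

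**Figure D2:**
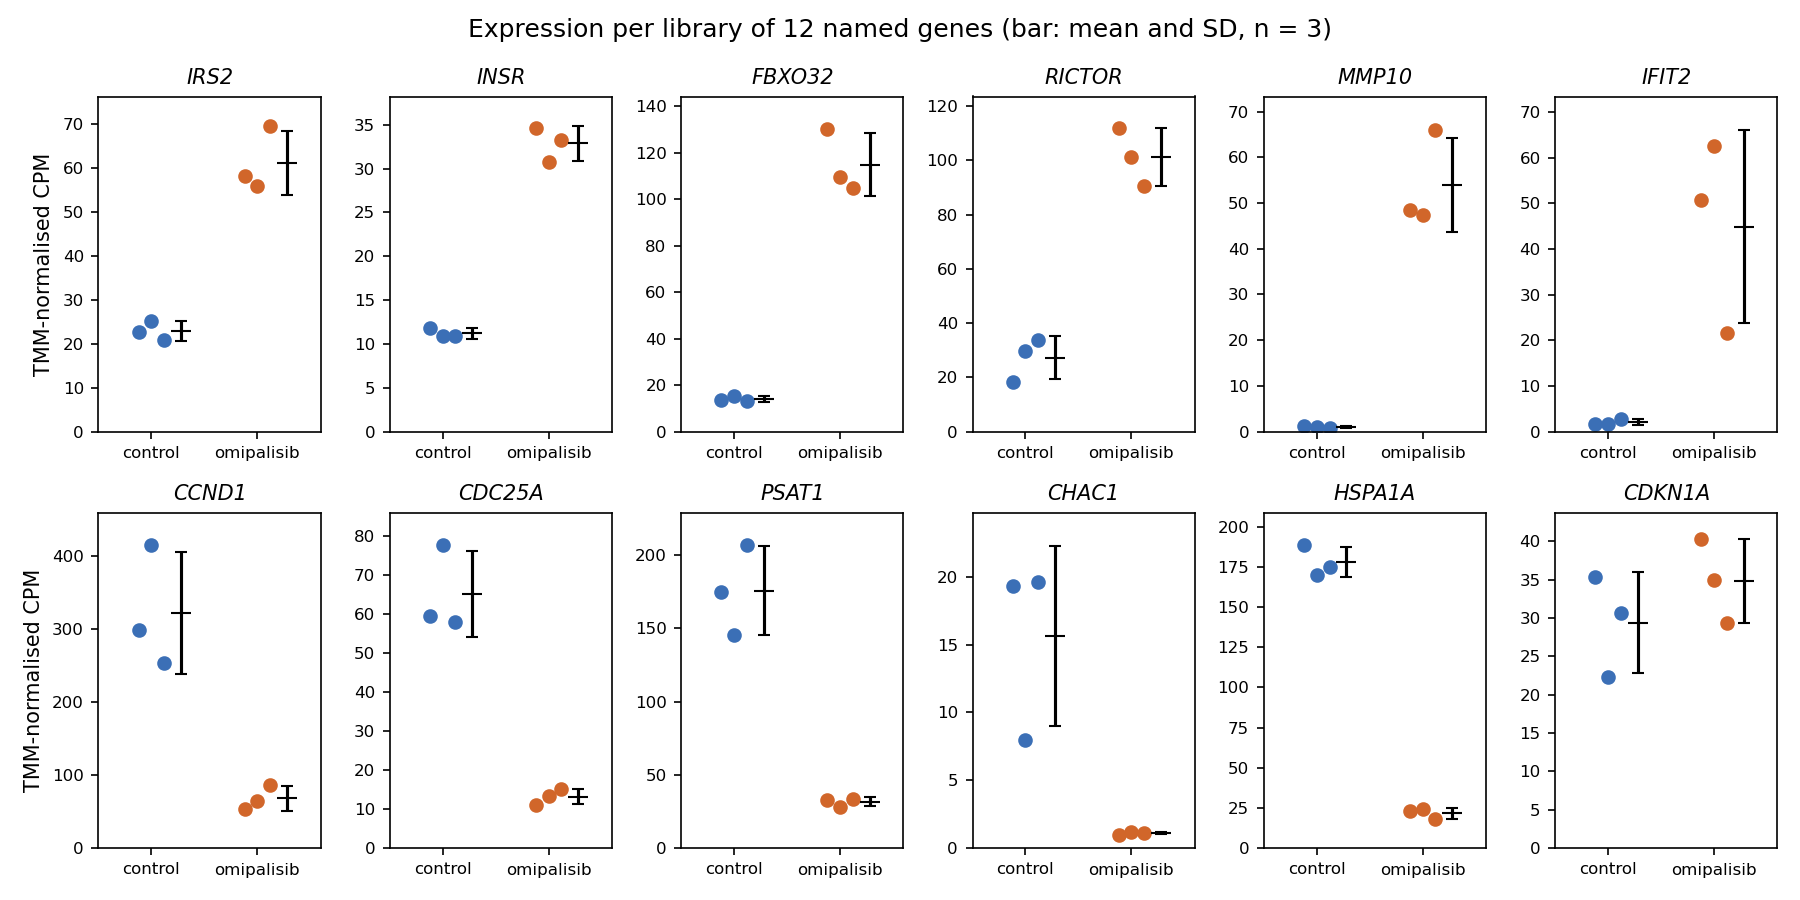
TMM-normalised CPM of 12 named genes in the 3 control (blue) and 3 omipalisib (orange) libraries, with the mean and SD of each group in black, each panel on its own linear axis from 0. Control and treated values overlap for CDKN1A (means 29.4 and 34.9 CPM) and in none of the other 11 panels.

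DNA replication and S phase genes fell together: 38 of 43 tested E2F targets fell and 0 rose, with the same counts adjusted over the list alone. Besides CDC25A, the replication factor genes MCM10 and CDC6 were 3.87-fold and 3.29-fold lower, and the transcription factor gene E2F2 3.12-fold lower. The list had the lowest camera p (adjusted p = 1.77e-25), and an adjusted p of 0.102 with an estimated correlation. The G1 cyclin gene CCND1 (gene 595) fell from 322 ± 83 to 67.8 ± 17.0 CPM (log2 fold change -2.25 ± 0.24), CCND3 was 2.49-fold lower and CCND2 1.79-fold lower. The CDK inhibitor gene CDKN1B (gene 1027) rose 1.62-fold. CDKN1A (gene 1026) did not pass, at 29.4 ± 6.6 against 34.9 ± 5.5 CPM (adjusted p = 0.331 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). MYC (gene 4609), a growth-promoting transcription factor gene, rose 1.85-fold, from 43.1 ± 1.8 to 79.8 ± 14.1 CPM.

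As a list, the 17 tested G1 cyclin, CDK and CDK inhibitor genes had 3 higher (CDKN1B, CDKN2A and RBL2) and 7 lower (also 3 and 7 adjusted over the list alone), with E2F4 1.69-fold lower. Camera gave an adjusted p of 0.0664 in the lower direction (0.207 with an estimated correlation), while the mean was -0.23 and the median 0.07 (-0.02, 0.03 and 0.10 without control 1, 2 and 3; -0.11 with length and GC offsets; 0.16 with library size only); without omipalisib 3 its adjusted p was 0.0471, and with no filter on low counts 0.0363. Of 38 mitosis genes, 4 rose and 9 fell, also adjusted over the list alone, with a camera adjusted p of 0.907 (0.973 with an estimated correlation). CDC20, an activator of mitotic exit, was 1.56-fold lower, the mitotic phosphatase gene CDC25C 1.51-fold higher, the kinase gene NEK2 1.42-fold higher and the topoisomerase gene TOP2A 1.81-fold higher. TOP2A had an adjusted p of 0.0473 by edgeR, and missed the threshold without control 3 (0.0628) or omipalisib 1, 2 or 3 (0.089, 0.0901 and 0.128). With scaling by library size only, 5 mitosis genes rose and 3 fell; 2 rose without omipalisib 2 and 11 without control 1, and 3 fell without omipalisib 1 or 2. With length and GC offsets 10 mitosis genes rose and 8 fell.

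Genes for making ribosomes fell, while the direction of ribosomal protein genes depended on the setting. Of 44 ribosome biogenesis genes, 30 fell and 1, NOB1, rose, as when adjusted over the list alone (camera adjusted p = 4.1e-15; 0.193 with an estimated correlation). The nucleolar factor gene NOP56 went from 199 ± 34 to 58.8 ± 6.2 CPM, URB2 was 2.75-fold lower, PNO1 2.68-fold lower and UTP15 2.47-fold lower. Of 78 ribosomal protein genes, 5 rose (RPL3, RPL10, RPL10A, RPL12 and RPL13A), 7 fell and 66 did not pass, with 2 higher and 6 lower adjusted over the list alone. RPS26, FAU, RPL35 and RPS15 were 1.84-fold, 1.42-fold, 1.34-fold and 1.31-fold lower. In edgeR, the RPL35 call was lost without omipalisib 1 (adjusted p = 0.0565) or omipalisib 3 (0.0519). With scaling by library size only, 9 ribosomal protein genes rose and 5 fell, and with RLE size factors 2 rose. The number that rose was 2, 1 and 1 without omipalisib 1, 2 and 3, and 2 without control 2 or 3; the number that fell was 3 without omipalisib 1 or 3 and 12 without control 1. The ribosomal protein list had a median log2 fold change of -0.02, which was 0.08 with scaling by library size only, 0.03 without control 3 and 0.01 without omipalisib 1 or 3, and from -0.05 to -0.02 without the other libraries, and a camera adjusted p of 0.68 (0.94 with an estimated correlation). Offsets for transcript length and GC content, added after the data were seen, moved the list to the higher side, with 32 higher and 7 lower, a median of 0.11 and a camera adjusted p of 0.0341.

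Amino acid and nucleotide supply genes fell as well. Of 34 targets of ATF4, a transcription factor of the amino acid response, 28 fell and 2 (SLC38A2 and ATF3) rose, also adjusted over the list alone (camera adjusted p = 4.52e-15; 0.187 with an estimated correlation); 1 rose without omipalisib 1 or 2 or control 1 or 2. CHAC1, a glutathione-degrading enzyme gene, fell from 15.7 ± 6.6 to 1.10 ± 0.11 CPM, JDP2 was 4.48-fold lower, and the mTOR regulator gene DDIT4 was 4.77-fold lower, with control values of 558, 207 and 638 CPM. Of 20 aminoacyl-tRNA synthetase genes, 13 fell and 1, DARS, rose, also adjusted over the list alone (camera adjusted p = 6.91e-08; 0.0551 with an estimated correlation). MARS was 2.90-fold lower, GARS 2.5-fold, AARS 2.03-fold and WARS 1.86-fold. Of 17 nucleotide synthesis genes, 13 fell and 0 rose (13 and 1 adjusted over the list alone), and the camera adjusted p was 5.19e-07 (0.102 with an estimated correlation); 8 fell without omipalisib 1 or 2. The cytidine synthesis gene CTPS1 fell from 149 ± 8 to 47.4 ± 3.5 CPM, and PRPS1, which encodes an enzyme that makes the ribose precursor of nucleotides, was 2.04-fold lower, PFAS 1.89-fold and UMPS 1.76-fold.

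Sterol and fatty acid synthesis genes, which SREBP transcription factors drive, were lower. Of 24 cholesterol synthesis genes, 14 fell and 1, TM7SF2, rose (18 and 1 adjusted over the list alone; camera adjusted p = 9.39e-07; 0.102 with an estimated correlation). The sterol sensor gene INSIG1 was 3.68-fold lower and HMGCS1 2.25-fold lower. Of 15 fatty acid synthesis genes, 9 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.000294; 0.143 with an estimated correlation). Fatty acid synthase, FASN, went from 1295 ± 316 to 494 ± 31 CPM, and the desaturase gene SCD from 720 ± 224 to 188 ± 58 CPM; ACLY was 2.02-fold lower and MID1IP1 1.75-fold lower.

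In central carbon metabolism, 9 of 22 glycolysis genes fell and 1, the glucose transporter gene SLC2A3, rose 2.04-fold (9 and 2 adjusted over the list alone; camera adjusted p = 0.0042; 0.415 with an estimated correlation). PGAM1 was 2.49-fold lower and hexokinase 2, HK2, 1.85-fold lower, and TPI1 1.49-fold lower. Of 37 oxidative phosphorylation genes, 17 fell and 0 rose (18 and 0 adjusted over the list alone), by small amounts, with a median log2 fold change of -0.23, or -0.13 with library size only (camera adjusted p = 0.000113; 0.32 with an estimated correlation). With scaling by library size only, 10 of these genes fell, and 8, 9 and 10 fell without omipalisib 1, omipalisib 3 and control 3. Length and GC offsets gave the oxidative phosphorylation list a median of -0.16 and a camera adjusted p of 0.0178. Of the 11713 genes with a length that passed a minimum of 5 CPM, the 10% with the shortest transcripts had a median of -0.18. UQCRFS1, a subunit of complex III, was 2.25-fold lower, and the complex I subunit genes NDUFS8, NDUFB3 and NDUFA9 were 1.48-fold, 1.44-fold and 1.40-fold lower. In the pentose phosphate pathway, 2 of 8 genes fell, RPIA (1.88-fold lower) and PGD (1.40-fold lower), and 0 rose, also adjusted over the list alone; the camera adjusted p was 0.282 (0.507 with an estimated correlation), and 2 rose with scaling by library size only or without control 1.

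Protein folding genes fell and autophagy genes rose. Of 15 heat shock genes, 14 fell and 0 rose (15 fell adjusted over the list alone; camera adjusted p = 3.22e-18; 0.0551 with an estimated correlation). The co-chaperone gene DNAJA1 was 3.97-fold lower and HSPH1 2.55-fold lower. Of 17 unfolded protein response genes, 11 fell and 2 (EDEM1 and DNAJC3) rose (11 and 3 adjusted over the list alone; camera adjusted p = 9.4e-05; 0.102 with an estimated correlation). The endoplasmic reticulum chaperone gene HSPA5 fell from 101 ± 12 to 42.0 ± 4.1 CPM, and SDF2L1, CRELD2 and SEC61B were 2.71-fold, 1.95-fold and 1.82-fold lower.

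Of 35 autophagy genes, 16 rose and 5 fell (19 and 7 adjusted over the list alone; camera adjusted p = 0.000102; 0.0715 with an estimated correlation). The autophagosome protein gene GABARAPL1 rose from 36.6 ± 7.1 to 186 ± 9 CPM, the cargo receptor gene SQSTM1 from 621 ± 60 to 1588 ± 88 CPM, ATG2A 3.48-fold and OPTN 2.76-fold. Those that fell were ATG3, ATG4A, ATG4B, ATG16L1 and ATG101; 3 fell without omipalisib 1, omipalisib 3 or control 3. Of 33 lysosome genes, 13 rose and 3 (ATP6V0D1, ATP6V0E1 and GUSB) fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.0168; 0.194 with an estimated correlation). The number that rose was 8 without omipalisib 1. The lysosomal protease gene CTSB rose 2.05-fold, SGSH 2.17-fold, NEU1 1.80-fold and the cholesterol transporter gene NPC1 1.80-fold.

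Genes of basal squamous epithelium rose, and genes of squamous differentiation fell. Of 19 basal genes, 11 rose and 1, the basal keratin gene KRT5, fell (11 and 2 adjusted over the list alone; camera adjusted p = 5.12e-06; 0.0887 with an estimated correlation). TP63, the transcription factor gene of basal squamous cells, rose from 116 ± 15 to 329 ± 39 CPM, the hemidesmosome linker gene DST from 147 ± 50 to 739 ± 35 CPM, and the desmosomal genes DSG3 and DSC3 2.54-fold and 2.49-fold. Of 17 differentiation genes, 8 fell and 1, EMP1, rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.0144; 0.415 with an estimated correlation). The suprabasal keratin gene KRT13 was 3.97-fold lower and the transcription factor gene GRHL1 3.01-fold lower; KRT16 and FLG were 2.06-fold and 1.67-fold lower. The KRT16 call (adjusted p = 0.0343 by edgeR) was lost without control 1 or 3 (0.0824 and 0.0794) or omipalisib 1, 2 or 3 (0.0897, 0.0555 and 0.101). Without control 1 the differentiation list had a camera adjusted p of 0.093, and with length and GC offsets 0.0816; 5 of its genes fell without omipalisib 1 or control 3.

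Markers of other cell types gave few measurable genes. The endothelial, fibroblast and leukocyte lists had 3, 2 and 3 tested members, too few for a list test, and 1 of each rose: CDH5, ACTA2 and CD68 (1, 2 and 1 adjusted over the list alone); without control 1, 2 fibroblast and 2 leukocyte genes rose, and without omipalisib 3, 2 fibroblast genes. CDH5, an endothelial cadherin gene, had 4 reads in all controls together and 48, 76 and 39 reads in omipalisib libraries 1, 2 and 3. ACTA2 rose 2.69-fold, a call lost in edgeR without omipalisib 1 or 2 (adjusted p = 0.0563 and 0.0528). CD68 rose 1.75-fold, lost in edgeR without control 2 or 3 (adjusted p = 0.0562 and 0.0674) or omipalisib 1 or 2 (0.0805 and 0.0807). Of 8 mesenchymal genes, 1, ZEB1, rose 1.92-fold and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.724; 0.849 with an estimated correlation); 2 rose without control 2, and 3 with library size only or with length and GC offsets. The ZEB1 call was lost in edgeR without control 1 or 3 (adjusted p = 0.0674 and 0.0961) or omipalisib 1, 2 or 3 (0.053, 0.0893 and 0.105). Of 5 columnar epithelium genes, KRT7 rose 1.71-fold and KRT8 was 1.5-fold lower, also adjusted over the list alone (camera adjusted p = 0.757; 0.896 with an estimated correlation; mean 0.03, median -0.23). That median turned to 0.31 without control 1 and to 0.19 with length and GC offsets, and was -0.15 without omipalisib 3 and -0.13 with library size only.

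Inflammatory and interferon-induced genes rose, unevenly between the treated libraries. Of 25 interferon response genes, 11 rose and 2, USP18 among them, fell (15 and 3 adjusted over the list alone; 5 fell with length and GC offsets; camera adjusted p = 0.00143; 0.415 with an estimated correlation). IFIT2 was at 50.6, 62.6 and 21.6 CPM in omipalisib libraries 1, 2 and 3, against 1.59 to 2.79 CPM in controls; the transcription factor gene IRF9 rose 3.46-fold. Of 17 NF-kB targets, 6 rose and 1, TNFAIP2, fell, also adjusted over the list alone (camera adjusted p = 0.0158; 0.32 with an estimated correlation). Besides IL6, the NF-kB subunit gene RELB rose 1.87-fold and the prostaglandin synthase gene PTGS2 2.23-fold. TRAF1 rose 1.85-fold, a call lost in edgeR without control 2 (adjusted p = 0.0523) or omipalisib 1, 2 or 3 (0.0561, 0.0842 and 0.103). Of 24 ERK output and immediate early genes, 11 rose and 2 (FOSL1 and SRF) fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.00288; 0.166 with an estimated correlation). Of these, 6 rose without omipalisib 1 or 2 and 7 without control 1. The ERK phosphatase gene DUSP6 rose 3.97-fold, from 11.95 ± 1.04 to 47.4 ± 9.4 CPM, and the feedback inhibitor gene SPRY1 2.26-fold. FOSB was at 109, 97.5 and 18.9 CPM in omipalisib libraries 1, 2 and 3 and at 15.7 to 16.7 CPM in controls. The FOSB adjusted p in edgeR was 0.0315, and from 0.0597 to 0.144 without control 1, 2 or 3 or omipalisib 1 or 2. DUSP1 rose 3.64-fold, and missed the threshold in edgeR without control 1 or 2 (adjusted p = 0.0524 and 0.0554).

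The other fixed lists held changed genes in both directions and did not pass camera. Of 18 hypoxia targets, 6 rose and 3 (P4HA2, HILPDA and AK4) fell (7 and 4 adjusted over the list alone), with MXI1 3.29-fold and NDRG1 2.85-fold higher and HILPDA 2.00-fold lower (camera adjusted p = 0.0929; 0.415 with an estimated correlation; 0.0209 by camera without omipalisib 3). Of 24 p53 targets, 5 rose (BBC3, TP53INP1, SESN1, GDF15 and SUSD6) and 4 fell (BAX, GADD45A, AEN and TIGAR); 6 and 4 passed adjusted over the list alone. Without omipalisib 1 or 2 edgeR called 0 of these genes higher, without omipalisib 3 it called 2, without control 1 or 3 it called 3, and with library size only 8. AEN was 3.93-fold lower and GDF15 rose 3.21-fold; the list's camera adjusted p was 0.757 (0.831 with an estimated correlation), with a median of 0.12 (0.07 without control 1 or 2, 0.21 with library size only), a mean of 0.01 and a test direction of lower. The edgeR call of GDF15 was lost without control 1 (adjusted p = 0.0643) or omipalisib 1 or 2 (0.0889 and 0.064), and that of BBC3 without control 1 (0.0535) or omipalisib 1, 2 or 3 (0.079, 0.11 and 0.0778).

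Of 21 BCL2 family and IAP genes, 7 rose and 6 fell (8 and 6 adjusted over the list alone); 4 rose without omipalisib 1 or 2, and 3 fell without omipalisib 1 or 3. The cell death activator genes HRK and BMF rose 2.65-fold and 2.60-fold, and the survival gene BCL2L1 was 1.72-fold lower (list camera adjusted p = 0.76; 0.896 with an estimated correlation). Of 20 NRF2 targets, 4 rose (GCLC, OSGIN1, FTL and FTH1) and 3 fell (GCLM, SRXN1 and SLC7A11), also adjusted over the list alone. Their camera adjusted p was 0.856 (0.909 with an estimated correlation), with a mean of 0.07 and a test direction of higher. The NRF2 median was -0.07, but 0.03 with library size only, 0.04 without omipalisib 1, -0.11 without omipalisib 3 and -0.01 without control 1 or 3 or with length and GC offsets. The number that fell was 1 without omipalisib 1 or 2 and 5 without control 1 or with length and GC offsets. The SLC7A11 call was lost in edgeR without control 3 (adjusted p = 0.0846) or omipalisib 1, 2 or 3 (0.0514, 0.115 and 0.0982). Of 13 YAP targets, 3 rose (CTGF, AMOTL1 and ARHGEF17) and 1, the coagulation factor gene F3, was 2.11-fold lower, also adjusted over the list alone (camera adjusted p = 0.839; 0.94 with an estimated correlation). In this list 3 genes fell without omipalisib 3 or with length and GC offsets, and 2 without control 3. AMOTL1, 1.19-fold higher, lost its edgeR call without any of the libraries but control 1 (adjusted p from 0.0633 to 0.163). Of 14 reference genes, 5 fell, among them ACTB, TBP, HPRT1 and GUSB, and 2 rose, B2M among them, also adjusted over the list alone (camera adjusted p = 0.117; 0.284 with an estimated correlation). ACTB, the beta actin gene often used to scale other measurements, fell from 6035 ± 947 to 2422 ± 126 CPM. Of the reference genes 1 rose without omipalisib 1 or 2 or control 2. B2M lost its edgeR call without control 2 (adjusted p = 0.0575) or omipalisib 1 or 2 (0.0817 and 0.0815).

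**Figure D3:**
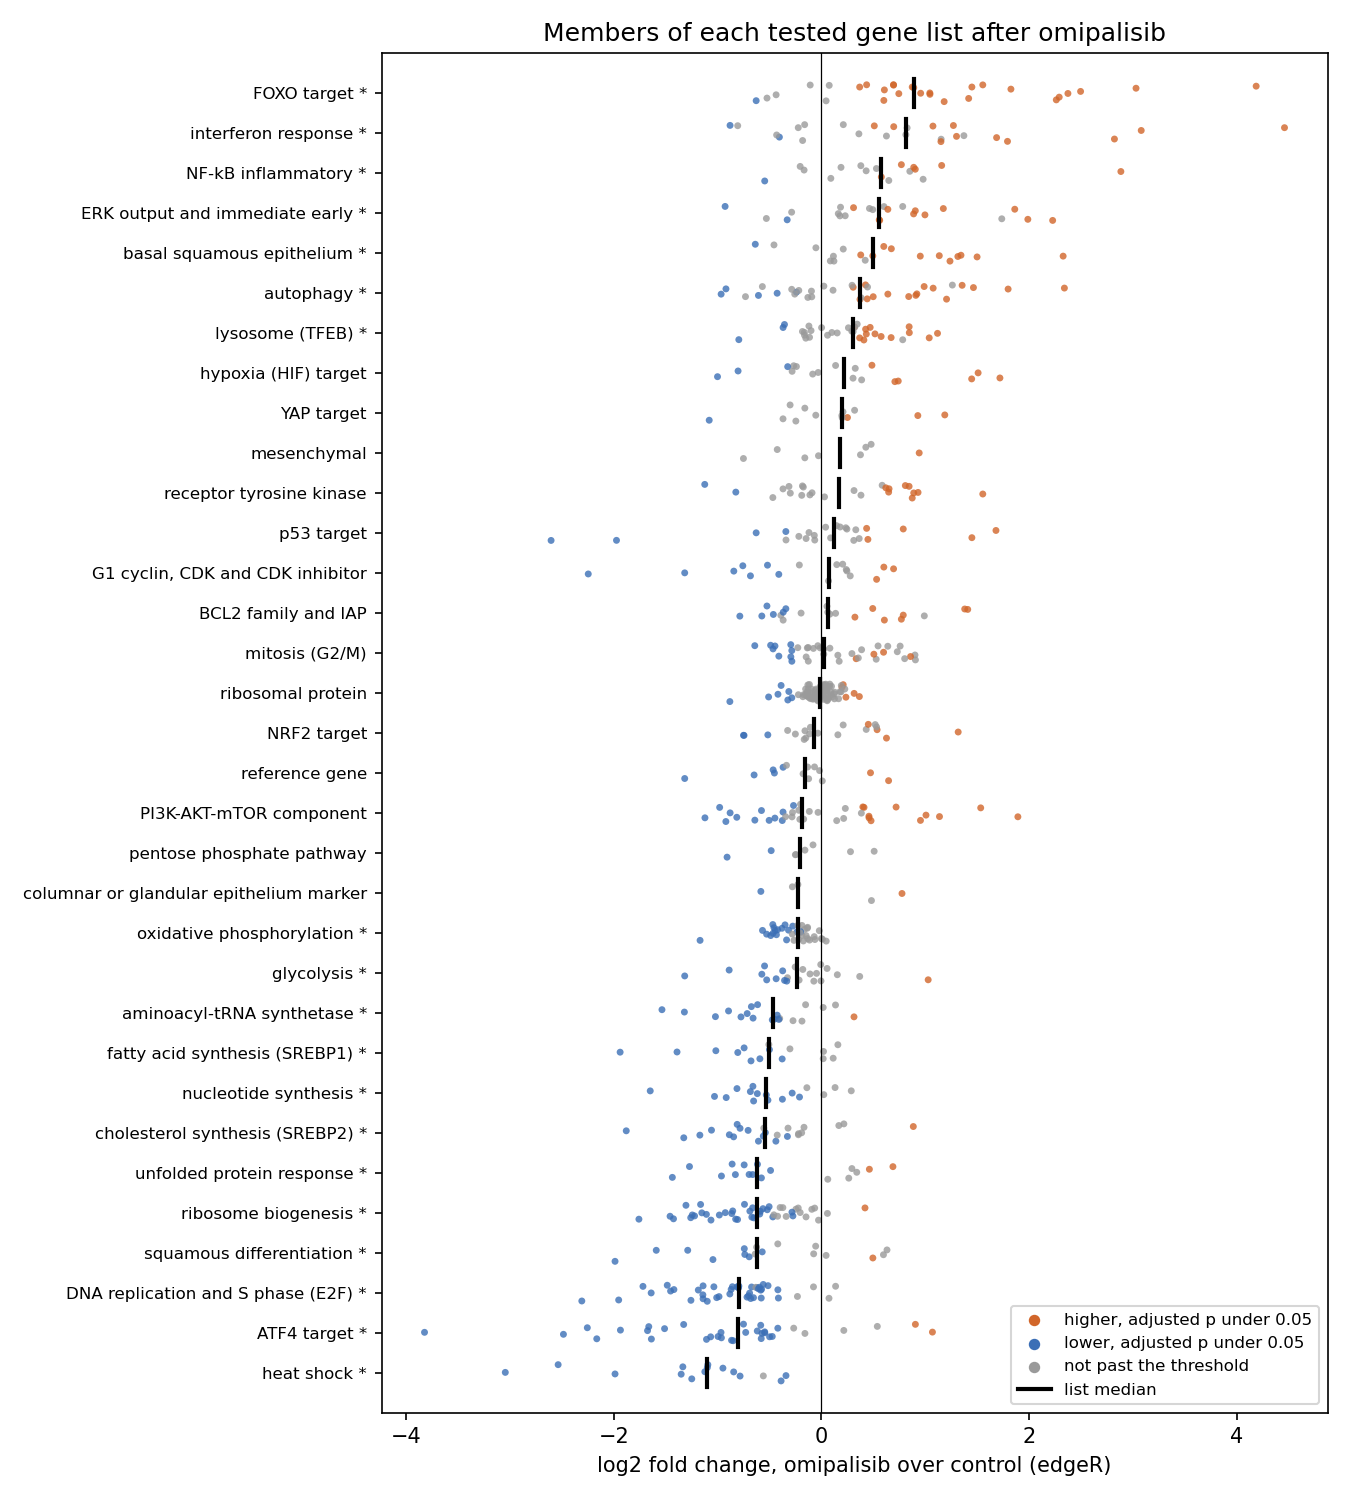
Log2 fold changes (omipalisib over control, edgeR) of the members of the 33 tested gene lists; each point is a gene, orange or blue where its adjusted p was under 0.05 and grey otherwise, and black bars are list medians, from -1.10 (heat shock) to 0.89 (FOXO targets). Asterisks mark the 19 lists that passed camera with its preset correlation; 0 passed with an estimated correlation.

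The number of genes that went against their list changed when a library was left out for tRNA synthetases (0 without omipalisib 1, 2 or 3 or control 3, 2 without control 1), cholesterol (0 without omipalisib 1 or 2), the unfolded protein response (1 without omipalisib 1, 2 or 3 or control 1 or 3), basal epithelium (2 without omipalisib 2 or control 2), interferon (1 without omipalisib 2, 3 without control 1 or 2), NF-kB (0 without omipalisib 1 or 3), ERK (0 without omipalisib 2, 1 without omipalisib 1 or 3 or control 1 or 2) and glycolysis (2 without control 1).

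Taken by list, 19 of 33 passed camera at an adjusted p of 0.05 with the preset inter-gene correlation of 0.01, 7 higher and 12 lower. With a correlation estimated from these libraries, 0 passed in camera, the lowest adjusted p being 0.0551, although 10 had an unadjusted p under 0.05; fry, which asks whether a list's genes moved one way without comparing them with other genes, called 23, including these 19.

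At the level of transcripts, 1190 of 79281 passed in edgeR's quasi-likelihood test, 408 higher and 782 lower with omipalisib. Of these, 1079 belonged to genes that passed at gene level, and 97.9% of those had their gene's direction. In 17 genes, 1 or more transcripts rose while another fell. This count rested on every library: leaving out any of the 6 gave 0 calls in edgeR, with 9380 to 11137 transcripts at an unadjusted p under 0.05, and DESeq2 called 10047 with all libraries. In simulated libraries edgeR called 0% of transcripts changed by a log2 fold change of 2, although their median estimate was 2.03. Only 200 of 68309 transcripts changed there, while 10536 of 79281 had an unadjusted p under 0.05 in edgeR here. That recovery need not hold for these data. As the calls rested on every library and differed so far between tools, the transcript count says little about how many changed.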

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

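Offsets for transcript length and GC content, and list tests without a minimum size, were chosen only after the result was seen; the other alternatives were fixed before. Of 143 genes that the naming rule picks, 142 passed with all libraries; 123 of these passed without each library in turn, 19 lost the call without at least 1, and 0 turned direction. Leaving out a library gave 3943 to 6900 called genes, 1885 to 3294 higher and 2058 to 3606 lower, 1131 to 1404 changed at least 2-fold (702 to 920 higher, 416 to 493 lower), 19 to 21 lists (7 to 8 higher, 11 to 13 lower), and 0 transcripts in either direction, with fewer samples in each. DESeq2 called 6057 genes, 5699 of them shared, and limma-voom 6076, 5916 of them shared. The at least 2-fold count fell to 674 (424 higher, 250 lower) with a filter of 10 CPM in 3 samples, which tests fewer genes, and to 608 (406 higher, 202 lower) on log2(FPKM + 1), where the scale, the test and the filter all differ and the cause was not tested. Among the genes the rule picks, calls were also lost without a filter (OASL, TP53RK, PIK3CA, FOSB, TOP2A, GDF15, KRT16 and AMOTL1), with limma-voom (OASL, FOSB and KRT16), on log2(FPKM + 1) (FOSB, SLC7A11 and KRT16), with offsets (FOSB and AMOTL1), with RLE size factors (AMOTL1) and with library size only (SLC7A11).

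Called transcripts went from 1190 to 652 without a filter (206 higher, 446 lower), which tests more entries, to 2940 with the 10 CPM filter (1415 higher, 1525 lower), which tests fewer, and to 10047 with DESeq2 (4857 higher, 5190 lower); with library size only, 495 were lower. For DESeq2 and library size only the cause was not tested. Lists called by camera went from 19 to 0 with an estimated correlation (0 higher, 0 lower), and the cause was not tested. Estimates for some called lists lay well above the preset 0.01, at 0.397 for ATF4 targets, 0.364 for ribosome biogenesis and 0.298 for E2F targets. The preset p-values of such lists assume far less correlation than was estimated. For the aminoacyl-tRNA synthetase and autophagy lists the estimated correlation was 0.00126 and -0.00268, not above the preset 0.01. A higher correlation therefore does not account for the lost calls of the aminoacyl-tRNA synthetase and autophagy lists. Values with an estimated correlation thus do not measure the effect of correlation alone. With length and GC offsets the ribosomal protein list turned from lower to higher (adjusted p = 0.0341 by camera; range over its alternatives 0.0341 to 0.962); the cause was not tested.

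Replicate numbers showed no sign of pairing the samples: deviations from group means correlated at -0.022, -0.087 and -0.12 for numbers 1, 2 and 3. Of 3 controls, 0 matched its own number best. A pairing could go unseen with 3 libraries per group. With a replicate block, edgeR called 5009 genes (2559 higher, 2450 lower) and 0 transcripts (0 higher, 0 lower; 7171 at an unadjusted p under 0.05), with fewer residual degrees of freedom. Under the block IFIT3 (adjusted p = 0.0572), DDIT4 (0.137), IRF9 (0.0848), OASL, TP53RK, FOSB, GDF15, KRT16 and AMOTL1 missed the threshold in edgeR, and the receptor tyrosine kinase and hypoxia lists passed camera (adjusted p = 0.0378 for each; ranges over their alternatives 0.00643 to 0.624 and 0.0209 to 0.415). It changed no other call of a gene that the rule picks or of a list. At 21277270 to 21829209 reads per library, genes under about 1 CPM limit the precision.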

Other observations

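Gene families and gene types in this part were picked after the gene results were seen. Camera p-values of the families were adjusted over the 12 picked families only, and the choice itself favours low values. The tests of the uneven interferon response and of transcript length were also chosen only after the result was seen. Those of noncoding RNAs and of other sample splits were set before. Mitochondrial ribosomal protein genes fell (55 of 78 fell, 1 rose, 0 without omipalisib 1, 2 or 3 or control 2 or 3; camera adjusted p = 2e-14; 0.061 with an estimated correlation), as did mitochondrial protein import genes (20 of 24 fell, 0 rose; camera adjusted p = 1.01e-12; 0.0558 with an estimated correlation). Proteasome subunit genes fell (25 of 38, 0 rose; camera adjusted p = 9.76e-08; 0.0664 with an estimated correlation), and so did CCT chaperonin genes (7 of 9, 0 rose; camera adjusted p = 4.51e-05; 0.137 with an estimated correlation). Tubulin genes fell (7 of 13, with TUBA1A higher, and 2 higher without control 1; camera adjusted p = 0.00139; 0.114 with an estimated correlation), as did keratin genes (8 of 18, with KRT7 higher; camera adjusted p = 0.00121; 0.245 with an estimated correlation).

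Of 15 metalloproteinase genes, a family picked because MMP10 and MMP13 led the rises, 6 rose, these included, and 1 fell, or 3 with length and GC offsets (camera adjusted p = 9.76e-08; 0.061 with an estimated correlation). KLF genes rose (10 of 14, 1 fell, 0 without omipalisib 1 or 2; camera adjusted p = 7.45e-06; 0.0609 with an estimated correlation), as did YPEL genes (YPEL1, YPEL2, YPEL3 and YPEL5 of 5; camera adjusted p = 8.08e-06; 0.0558 with an estimated correlation) and metallothionein genes (MT1E, MT1F and MT2A of 5; camera adjusted p = 4.51e-05; 0.0609 with an estimated correlation). Replication-dependent histone genes rose (14 of 33, 0 fell, 1 without control 3; camera adjusted p = 0.000458; 0.0984 with an estimated correlation), although poly-A selection captures few of their transcripts. Of 405 ZNF zinc finger genes 83 rose and 35 fell (camera adjusted p = 0.0689; 0.408 with an estimated correlation); without omipalisib 1, 2 and 3, 42, 46 and 49 rose and 16, 19 and 21 fell. Among the KLF and YPEL genes that rose, KLF2, KLF6 and YPEL3 are also FOXO list members, so both families overlap that list. Median directions of these 12 families did not flip under RLE size factors, library size only, length and GC offsets or without any 1 library.

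With 3 samples against 3, the 10 splits are too few for a share under 0.05. The real split gave 6016 genes, 19 lists and 1190 transcripts. The other splits gave 0 genes, 6 to 15 lists and 0 transcripts. Each of them mixed treated and control libraries in both groups, so the treatment difference widened the spread within groups. They therefore do not show how many calls arise without a treatment difference. In edgeR the other splits had 114 to 354 genes and 1273 to 1716 transcripts at an unadjusted p under 0.05. In each case 1 of 10 splits, the real one, gave as many.

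Interferon list medians against the control mean were 0.38 in omipalisib 3 and 0.84 and 0.80 in omipalisib 1 and 2. Depth argues against a shallower library, since its total was 1.005 times the mean of the others. A weaker overall response stays open: the ratio of its response to the others was 0.884 for FOXO, E2F and ATF4 list genes and 0.622 for interferon genes, a difference of 0.262 (95% interval -0.139 to 0.533). The ratio of 0.622 is another measure than the ratio of the interferon list medians given above, which would be lower. The difference therefore depends on the measure. Stress at harvest that differed between dishes also stays open. The range of 6 immediate early genes, not all past the threshold, among controls was 0.396 of that among treated libraries. Nor do the labels say which library came from which dish. No biological explanation was tested.

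Longer transcripts tended to rise and shorter ones to fall, among the 11713 genes with a length that passed a minimum of 5 CPM. Of the 10% of these genes with the shortest transcripts 11% rose and 37.5% fell, and of the 10% with the longest 31.7% rose and 11.3% fell. Length and GC bias as the whole cause of the list changes is argued against by the 18 of 19 lists that stayed called with offsets. Quality that varied from dish to dish regardless of treatment stays open. Slopes of log2 CPM on transcript length parted by group, with a gap 1.19 times the larger range within a group. That parting is the pattern itself, and which library came from which dish is not known. For squamous differentiation, length and GC bias stays open. The list's median went from -0.62 (SD 0.74) to -0.55 (SD 0.74), a ratio of 0.886. Its camera adjusted p went from 0.0144 to 0.0816 (range over its alternatives 0.00132 to 0.415), and what ended the call was not tested. Whether the drug changed RNA quality, or the transcripts of long genes themselves, was not tested, as either would follow treatment.

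Genes typed as lncRNA, called noncoding here, were more often higher than lower: 376 of 477 called were higher (78.8%, 95% interval 74.9 to 82.4). The share of called protein-coding genes was 46.0%, and with library size only the shares were 84.9% and 58.0%. Of called transcribed pseudogenes 80 of 99 were higher (80.8%), and of called genes without a gene type 166 of 242 (68.6%). The excess was thus not limited to lncRNA genes. Without omipalisib 1 and 2 the noncoding calls numbered 305 and 288 (79.3% and 77.8% higher), and with length and GC offsets 260 (71.9% higher). The intervals given here treat genes as independent and do not cover the spread between libraries or scalings. The shares of 84.9% and 71.9% lie outside the interval of the main fit. Low expression and length as the whole cause are argued against only within the main fit, where 66% of coding genes matched on both were higher. This was closer than all coding genes to 78.7% (74.7 to 82.3) of noncoding genes with a length. Reads of overlapping coding genes as the whole cause are argued against by the 262 called noncoding genes that overlap none, of which 87.4% were higher (82.8 to 91.2). A drug effect on noncoding RNA may be among the causes, as a hypothesis only; reads from introns were not tested.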
